A study of Homo sapiens with 12 samples.

How the data were processed

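Polyadenylated RNA was sequenced from the triple-negative breast cancer cell lines SUM159, MDAMB231 and HCC1806 after 72 h with DMSO, JQ1, GSK2801 or both, giving 12 libraries. Per the labels' protocols, HCC1806 grew in RPMI 1640 with serum, and the other lines in DMEM/F12 with serum, insulin and hydrocortisone. The labels differ on the library kit, with KAPA Stranded mRNA-seq in some places and Illumina TruSeq RNA in others, so the kit is left open. Per the submitters' processing notes, the authors aligned reads with STAR 2.4, counted them with Salmon 0.60 and used the hg38 build. The gene annotation, any filter and the scaling step are not described.

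Each deposited file held a gene symbol and 1 value per gene, and its unit was taken as signal, meaning estimated read counts that the authors had scaled by 1 factor per library. This was checked on the values, which were never negative and mostly not whole. The 75th percentile of the values above 0 was 1663.93 in each of the 12 libraries. Between 67.1% and 69.2% of the values above 0 were whole multiples of 1 step per library, within a tolerance of 0.02. That step, the value of 1 read, gave 24200000 to 46800000 estimated reads per library. The 10 genes with the highest values held 4.37% to 7.58% of the signal. Values are therefore relative to each library's upper quartile, and no counting interval was computed from them.

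Each file held 28539 entries, of which 27 had symbols that a spreadsheet had turned into dates. These 27 held 0.168% to 0.218% of the signal and were left out of the gene comparisons, since a date does not name a gene uniquely. Of the other 28512 genes, the 14232 with a mean value of at least 10 over the 12 libraries were tested. Of these, 14030 (98.6%) had the symbol of a GENCODE v29 gene, and positions come from that annotation on the same build. Symbols such as HIST2H4A and HIST2H4B name near-identical genes whose reads Salmon divides between them, so the value of each single copy is uncertain. The same holds for readthrough symbols such as RNASEK-C17orf49 and PALM2-AKAP2.

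The values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3. The plan allowed for count models had the files held unscaled counts. As the unit is signal, limma with a variance trend was used throughout. The model held the cell line as a block (3 levels) and the treatment (4 levels), with 6 residual degrees of freedom and 3.02 prior degrees of freedom. The replicate numbers pair libraries by cell line, so replicate 1 is SUM159, replicate 2 MDAMB231 and replicate 3 HCC1806. The pairing was checked by correlating libraries, and each library correlated more with those of its own line (0.935 to 0.993) than with those of other lines (0.685 to 0.810). With 1 library per line and treatment, the p-values of this model measure the spread between lines and not that between cultures of 1 line. The JQ1 and combination libraries of a line share that line's own JQ1 effect. Where this effect differs between lines, the residual degrees of freedom are not independent. The p-values of contrasts between libraries with and without JQ1 may then be too small. Fold changes are means of the log2 differences over the 3 lines, given with the standard error (SE) of the moderated fit.

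A total of 6 contrasts were tested in that model: JQ1, GSK2801 and their combination against DMSO, the combination against JQ1, the combination against GSK2801, and the departure from additivity on the log2 scale. A further model gave each line its own JQ1 effect, averaged over the absence and presence of GSK2801, and the reverse for GSK2801, with 3 residual and 4.48 prior degrees of freedom, and compared HCC1806 with the mean of the other lines. The residual of this further model is each line's departure from additivity. Its p-values thus measure neither the spread between lines nor that between cultures of a line. P-values were adjusted over all tested genes of a contrast by the Benjamini-Hochberg method, with a threshold of 0.05. Within each line, log2 ratios to DMSO were computed with no test.

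Before the data were examined, 27 gene lists were written, and 26 of them had at least 5 measured members. No mitochondrially encoded gene was measured, so that list was not tested. The lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a contrast, and again with the correlation estimated from the data. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. Camera compares a list with the other genes, so its direction can differ in sign from the list's median or mean. Medians within a line were set against 10000 random lists matched on mean value. Shared responses were compared with 100 simulations of unchanged groups that shared their DMSO libraries.

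The genes named were chosen by a rule fixed before the data were examined. Per contrast it took the 10 largest rises and the 10 largest falls among genes that passed, moved the same way in the 3 lines and had a mean value of at least 50. Where none passed, it took the 3 genes of smallest p in each direction. For the non-additive and line contrasts it took up to 5 each way. It further took up to 4 members of each list with the largest change, any passing member, and the 3 largest rises and falls per line and treatment. Genes it always included were HEXIM1, MYC, BRD2, BRD3, BRD9, BAZ2A, BAZ2B, FOSL1, CCND1, CDKN1A, BCL2, BIRC5 and MKI67. A few of the genes so chosen are not reported here.

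The models were tested on simulated data of the same design, with 14232 genes of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. Of genes changed 4-fold, the model found 83.3% for JQ1, 80.3% for GSK2801, 84.8% for the combination, 77.3% for the combination against JQ1 and 68.2% for the departure from additivity. Of genes changed by 1.5-fold it found 22.4%, 23.9%, 10.4%, 16.4% and 0%. Between 3 and 10 unchanged genes were called per contrast. All 5 shifted lists were called and none of the 15 unshifted lists. The simulated noise was independent between genes and libraries. For the treatment contrasts no JQ1 effect that differs between lines was simulated. The false calls therefore do not test p-values made too small by such differences. Nor does the simulation test calls in lists whose members vary together, such as mitosis. Its estimated correlation was 0.963 in the model with an effect for each line.

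The alternatives were other pseudocounts, no filter and a stricter low-value filter, rescaling by the trimmed mean of M values (TMM, trimming 30% and 5%), quantile normalization, no variance trend, a threshold of 1.5-fold within the test, only the libraries of the compared groups, no block for the line, and leaving out each line or library. Added after the data were seen were voom weights and a block for each combination of line and JQ1. TMM factors lay between 0.950 and 1.06. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Outlier tests were not run, as groups held 3 libraries.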

Results

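RNA was sequenced from 3 triple-negative breast cancer cell lines treated for 72 h with the vehicle DMSO, with JQ1, with GSK2801, or with both. JQ1 blocks the bromodomains of BET proteins such as BRD2 and BRD3, which bind acetylated histones, and GSK2801 blocks those of the chromatin proteins BAZ2A and BAZ2B. The lines were SUM159, MDAMB231 and HCC1806, with 1 library per line and treatment, so each of the 4 treatments had n = 3 lines. JQ1 was given at 300 nM to SUM159, 100 nM to MDAMB231 and 500 nM to HCC1806, and GSK2801 at 10 µM to each. HCC1806 also grew in another medium, so its line, medium and JQ1 dose cannot be told apart. The 12 libraries held 24200000 to 46800000 estimated reads and 15743 to 16774 genes above 0. Values are the deposited signal, scaled to 1 upper quartile in every library, and 14232 genes were tested with limma. Changes below are mean log2 fold changes over the 3 lines with their SE, and the DMSO libraries of the same lines are the background.

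JQ1 against DMSO addressed what the BET inhibitor did alone. HEXIM1, which inhibits the elongation factor P-TEFb and is a widely used marker of BET inhibition, rose 2.35-fold (log2 1.23 ± 0.08, n = 3 lines, adjusted p = 7.0e-04). Its value went from 2928 to 7082 in SUM159, from 3018 to 6483 in MDAMB231 and from 2510 to 6270 in HCC1806. BRD2 rose 2.02-fold (1.02 ± 0.12) and BRD3 1.24-fold (0.31 ± 0.09). CDKN1A, which encodes the cell cycle inhibitor p21, rose 2.86-fold (1.51 ± 0.21), and the anti-apoptotic gene BCL2 fell by 0.80 ± 0.17. MYC (−0.55 ± 0.38) and FOSL1 (−1.28 ± 0.65) did not pass, and their log2 ratios were −1.64 and −3.23 in HCC1806 against 0.10 and −0.19 in SUM159 and −0.12 and −0.43 in MDAMB231. CCND1 (0.55 ± 0.30), MKI67 (−0.70 ± 0.47), BIRC5 (−0.39 ± 0.36), BRD9 (−0.20 ± 0.12), BAZ2A (0.04 ± 0.18) and BAZ2B (−0.14 ± 0.18) did not pass either. Without HCC1806 the adjusted p was 0.0526 for BRD2 and 0.0697 for CDKN1A, and with a threshold of 1.5-fold it was 0.119 and 0.0706. BRD3 no longer passed without any 1 of the lines (0.0911 to 0.23), nor BCL2 without MDAMB231 (log2 −0.65, 0.126) or HCC1806 (log2 −0.77). With the threshold of 1.5-fold neither BCL2 (0.933) nor BRD3 passed. BRD3 was also lost with no low-value filter (0.0627) and with no variance trend (0.0716).

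The largest rise with JQ1 was that of EFR3B, a plasma membrane protein gene on chromosome 2 (25042130 to 25159137), at 58.8-fold (5.88 ± 0.61, adjusted p = 0.00125). The neuronal cytoskeleton gene DPYSL3 rose 26.2-fold (4.71 ± 0.68) and the neural adhesion gene L1CAM 13.2-fold (3.73 ± 0.63). YPEL1 (3.51 ± 0.25), MAFA, a transcription factor of pancreatic beta cells (3.26 ± 0.37), the protease gene CAPN5 (3.04 ± 0.33), C14orf37 (3.60 ± 0.52) and ZDHHC11B (3.09 ± 0.64) also rose. The largest fall was that of IL7R, the interleukin-7 receptor gene on chromosome 5 (35852695 to 35879603), which was 85.5-fold lower (−6.42 ± 0.74, adjusted p = 0.00143). HAS2, a hyaluronan synthase gene, fell by 4.03 ± 0.32, and the phosphatase gene PTPN22 by 4.52 ± 0.65. NAV3 (−4.41 ± 0.67), MYOSLID (−3.93 ± 0.50), SPOCD1 (−4.25 ± 0.80), the stress gene NUPR1 (−3.92 ± 0.74), the long noncoding RNA CCAT1 (−4.70 ± 1.06), RGS4 (−4.84 ± 1.42) and IL1B (−3.90 ± 1.21) fell too. ZDHHC11B is listed at 0 in DMSO for SUM159 and MDAMB231, RGS4 with JQ1 for SUM159 and HCC1806, and PTPN22, SPOCD1 and NUPR1 with JQ1 for HCC1806, so these folds depend on the pseudocount. EFR3B, L1CAM and MAFA have values near 0 in DMSO in 1 line or more. MYOSLID, CCAT1 and IL1B have such values with JQ1. Their folds depend on it too, here and below. Of the 20 largest changes, 9 no longer passed without SUM159, 3 without MDAMB231 and 10 without HCC1806. RGS4 (adjusted p = 0.0549 to 0.188), IL1B (0.0744 to 0.215) and ZDHHC11B (0.0513 to 0.0807) were lost without any 1 line, whereas EFR3B, YPEL1, MAFA, CAPN5, IL7R, HAS2 and PTPN22 passed in each case.

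Histone genes whose transcripts are polyadenylated, and linker histone genes, rose as a group with JQ1. Of 18 measured, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 2.9e-08; adjusted p = 0.580 with an estimated correlation). Examples were the core histone genes HIST2H2BE (2.75 ± 0.37) and HIST1H2AC (2.71 ± 0.38) and the linker histone genes HIST1H1C (1.74 ± 0.44) and H1F0 (1.56 ± 0.35). The list median was 1.63 in SUM159, 0.62 in MDAMB231 and 2.69 in HCC1806. The near-identical copies HIST2H4A (3.59 ± 0.63) and HIST2H4B (4.81 ± 0.97) on chromosome 1, at 149832659 to 149839767 and 149854045 to 149861210, were among the 20 largest changes, though their separate values are uncertain and HIST2H4B is listed at 0 in DMSO for MDAMB231. Autophagy and lysosome genes rose as well, with 9 of 33 up and 2 down (13 and 2 adjusted over the list alone; median 0.37; adjusted p = 1.6e-04; adjusted p = 0.580 with an estimated correlation). They included the autophagy kinase gene ULK1 (1.36 ± 0.19) and the autophagosome gene MAP1LC3B (0.97 ± 0.09), while TFEB, a regulator of lysosome genes, fell by 0.91.

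Genes of ribosome biogenesis and RNA polymerase I fell with JQ1. Of 54 measured, 36 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of −0.64 (adjusted p = 3.0e-14; adjusted p = 0.580 with an estimated correlation). The RNA polymerase I subunit gene ZNRD1 (−1.44 ± 0.20), the small nucleolar ribonucleoprotein gene GAR1 (−1.15 ± 0.15) and the rRNA methyltransferase gene FBL (−0.91 ± 0.08) were among them. Type I interferon response genes fell in 11 of 36 cases and rose in 3 (14 and 3 adjusted over the list alone), with a median of −0.78 (adjusted p = 0.0368; adjusted p = 0.825 with an estimated correlation). The antiviral genes OASL (−3.06 ± 0.71) and IFI44 (−2.18 ± 0.20) fell and the interferon regulator IRF7 rose (1.95 ± 0.29). In the NF-kB and secretory inflammatory list, 7 of 32 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of −0.87 (adjusted p = 0.0182; adjusted p = 0.580 with an estimated correlation), among them the cytokine genes CSF2 (−4.05 ± 0.53) and IL1A (−3.07 ± 0.77). CSF2 is listed at 0 with JQ1 in SUM159 and HCC1806, so its fold depends on the pseudocount. The interferon call ended with the stricter low-value filter (0.0530), without SUM159 (0.0663) and without the block for the line (0.0613), and the NF-kB call with the stricter filter (0.0530) and without MDAMB231 (0.0960).

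The other 21 lists did not pass for JQ1, but many held single genes that did. Over all 14232 tested genes 1355 rose and 1868 fell, so a count near those shares says little about its list. Of 24 p53 targets and cyclin-dependent kinase inhibitors, 6 rose and 3 fell (8 and 3 adjusted over the list alone), TP53INP1 most (2.43 ± 0.53). In the hypoxia and glycolysis list 7 of 26 rose and 3 fell (7 and 4 adjusted over the list alone), with CA9 at −3.17 and NDRG1 at 1.42. CA9 is listed at 0 with JQ1 in MDAMB231. In the ATF4 and endoplasmic reticulum stress list 1 of 29 rose and 8 fell (1 and 8), including ATF4 itself (−1.02). Cholesterol synthesis genes rose in 2 and fell in 6 of 29 cases (2 and 6), ETS family genes fell in 4 of 20 (4), and ERK output genes rose in 1 and fell in 5 of 27 (3 and 5). Among AP-1 factors 1 of 12 rose and 2 fell (4 and 2), JUND rising by 1.53, and among bromodomain proteins and partners 6 of 37 rose and 3 fell (6 and 5). For apoptosis regulators 3 of 27 rose and 4 fell (3 and 4), with the pro-apoptotic genes BMF (1.79 ± 0.55) and BCL2L11 (1.06) up. Epithelial and keratinocyte genes gave 4 up and 1 down of 34 (2 and 1), mesenchymal and matrix genes 2 and 0 of 36 (2 and 0), NRF2 and aryl hydrocarbon receptor targets 4 and 1 of 22 (4 and 2), and antigen presentation genes 2 and 2 of 20 (2 and 2). Neuronal genes gave 4 and 0 of 13 (4 and 1), BET inhibitor marker genes 3 and 3 of 12 (4 and 3), ribosomal protein genes 1 and 3 of 56 (0 and 0), DNA replication genes 0 and 3 of 45 (0 and 3), and mitosis genes 0 and 0 of 41 (0 and 0; median −0.44). Markers of other cell types gave 1 up and 1 down of 14 for luminal breast (0 and 1) and 0 and 0 for 8 blood and endothelial and 9 fibroblast and adipocyte genes (0 and 0). Median, mean and test differed in sign in 7 of the 26 lists, none of them passing: the BET inhibitor marker genes had a median of 0.10 and a mean of −0.18, and the AP-1 factors 0.23 and −0.01.

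In all, 3223 genes passed for JQ1, 1355 higher and 1868 lower. The same sign in the 3 lines was held by 3220 of them and by 7196 of all 14232 tested genes. Passing favours genes with the same sign, so the first count is no separate evidence, here and below. An unadjusted p below 0.05 was held by 5301 genes, where chance gives 712. At least 2-fold changes were seen for 440 of the higher and 567 of the lower genes. The share that was lower depended on the scaling, being 58.0% as deposited, 46.7% after TMM rescaling (1679 higher, 1472 lower) and 45.9% after quantile normalization (1726 and 1462). The count was 1643 without SUM159, 1532 without MDAMB231 and 402 without HCC1806, and with single libraries left out it was 1713 (MDAMB231 DMSO), 1647 (MDAMB231 JQ1), 1785 (HCC1806 DMSO) and 1493 (HCC1806 JQ1). It was 755 with only the 6 libraries compared, 120 with a threshold of 1.5-fold and 0 without the block for the line (893 at unadjusted p below 0.05, limma).

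**Figure D1:**
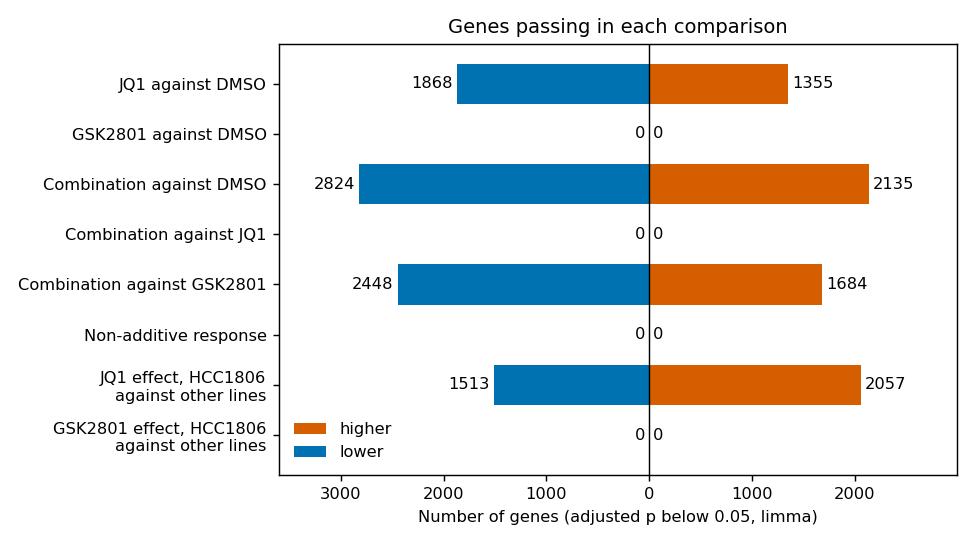
Bars give the number of genes past an adjusted p of 0.05 (limma) that were higher (above 0) or lower (below 0) in each of the 8 comparisons of the 12 libraries. Counts stand at 3223 for JQ1, 4959 for the combination and 4132 for adding JQ1 to GSK2801, at 3570 for the JQ1 effect in HCC1806 against the other lines, and at 0 for the other 4 comparisons.

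GSK2801 against DMSO addressed what this inhibitor did alone. Which bromodomains it blocked in these cells was not measured. No single gene passed. The genes of smallest p with higher values were THEM6 (0.36 ± 0.08), the fatty acid oxidation gene CPT1A (0.38 ± 0.09) and the lipoprotein receptor gene VLDLR (0.82 ± 0.21). Those with lower values were GPR176 (−0.58 ± 0.13), ANAPC15 (−0.45 ± 0.11) and the growth factor gene PDGFB (−1.01 ± 0.28), each with an adjusted p of 1.00 and the same sign in 3 of 3 lines. HEXIM1 stood at 0.04 ± 0.08, BRD2 at 0.30 ± 0.12, MYC at 0.25 ± 0.38, BAZ2A at 0.01 ± 0.18 and BAZ2B at 0.09 ± 0.18. The limma count of 0 went with 161 genes at an unadjusted p below 0.05, where chance gives 712. It stayed 0 with only the 6 libraries compared (1882 unadjusted), and, in fits chosen after the data were seen, with voom weights (179) and with a JQ1 effect for each line (1250).

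Of the 26 lists, 9 passed the preset-correlation test for GSK2801 alone, by small shifts, and 0 with an estimated correlation. The NRF2 and aryl hydrocarbon receptor targets had a median of 0.20 (adjusted p = 5.0e-05; adjusted p = 0.413 with an estimated correlation), with the aryl hydrocarbon receptor targets CYP1A1 at 1.02 ± 0.46 and CYP1B1 at 1.05 ± 0.39. The hypoxia and glycolysis list had a median of 0.15 (5.0e-05; adjusted p = 0.413 with an estimated correlation), with ANGPTL4 at 1.53 ± 0.48. Autophagy and lysosome genes stood at 0.10 (2.9e-04; adjusted p = 0.413 with an estimated correlation), with the autophagy receptor gene SQSTM1 at 0.41, and ATF4 and endoplasmic reticulum stress genes at 0.07 (0.00510; adjusted p = 0.413 with an estimated correlation). Ribosomal protein genes stood at 0.06 (0.00590; adjusted p = 0.895 with an estimated correlation) and histone genes at 0.19 (0.0289; adjusted p = 0.895 with an estimated correlation). Lower medians were found for the interferon list (−0.14, 0.00590; adjusted p = 0.503 with an estimated correlation), the NF-kB list (−0.14, 0.0141; adjusted p = 0.413 with an estimated correlation) and DNA replication (−0.09, 0.0105; adjusted p = 0.895 with an estimated correlation). In each of the 26 lists 0 members passed, over all genes or adjusted over the list alone. Without MDAMB231 the ATF4 (0.0909), NF-kB (0.329), histone (0.0759), ribosomal protein (0.210) and interferon (0.0909) calls ended. The replication and histone calls ended without SUM159 (0.293 and 0.173), the ATF4 call without HCC1806 (0.0750) and the ribosomal protein call after quantile normalization (0.708).

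The combination against DMSO addressed the response to both inhibitors. HEXIM1 rose 3.23-fold (1.69 ± 0.08, n = 3 lines, adjusted p = 6.6e-05), BRD2 2.84-fold (SE 0.12 on the log2 scale), BRD3 1.31-fold (0.39 ± 0.09) and CDKN1A 3.19-fold (1.67 ± 0.21), and BCL2 fell by 0.84 ± 0.17. EFR3B rose 92.5-fold (6.53 ± 0.61) and DPYSL3 37.5-fold (5.23 ± 0.68). The microtubule gene MAP1A (4.13 ± 0.65), MAFA (4.08 ± 0.37), BAIAP3 (4.05 ± 0.37) and C14orf37 (4.45 ± 0.52) rose, as did the histone genes HIST1H2BD (4.06 ± 0.27), HIST2H4A (4.90 ± 0.63), HIST2H4B (5.78 ± 0.97) and HIST2H2AA4 (4.48 ± 1.08). IL7R was 72.1-fold lower (−6.17 ± 0.74) and HAS2 26.1-fold lower (−4.71 ± 0.32). CCAT1 (−5.83 ± 1.06), NAV3 (−4.92 ± 0.67), the integrin gene ITGA10 (−4.73 ± 0.85), MYOSLID (−4.67 ± 0.50), HNF4G (−4.52 ± 0.59), FAM196B (−4.45 ± 0.56), SFTA1P (−4.38 ± 0.40) and NUPR1 (−4.19 ± 0.74) fell. HIST2H4B (DMSO, MDAMB231), HIST2H2AA4 (DMSO, HCC1806), CCAT1 and MYOSLID (combination, MDAMB231), and CCAT1, ITGA10 and NUPR1 (combination, HCC1806) are listed at 0, so their folds depend on the pseudocount. MYC (−0.43 ± 0.38), FOSL1 (−1.19 ± 0.65), CCND1 (0.74 ± 0.30), MKI67 (−1.30 ± 0.47), BIRC5 (−0.88 ± 0.36), BRD9 (−0.33 ± 0.12), BAZ2A (0.07 ± 0.18) and BAZ2B (−0.23 ± 0.18) did not pass. HIST2H2AA4 was lost without SUM159 (adjusted p = 0.112), NUPR1 without HCC1806 (0.0665), BCL2 without MDAMB231 (0.0815) and BRD3 without MDAMB231 (0.0648) or HCC1806 (0.0698). With a threshold of 1.5-fold HIST2H2AA4 (0.0586), BCL2 (0.493) and BRD3 were lost.

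With the combination 8 lists passed, and 0 did with an estimated correlation. Histone genes rose in 13 of 18 cases and fell in 0 (15 and 0 adjusted over the list alone; median 2.85; adjusted p = 4.3e-09; adjusted p = 0.633 with an estimated correlation), with HIST1H1C at 3.04 ± 0.44 and HIST2H2BE at 3.83 ± 0.37. Autophagy and lysosome genes rose in 20 of 33 and fell in 1 (21 and 1; median 0.55; adjusted p = 1.2e-07; adjusted p = 0.633 with an estimated correlation), with the lysosomal genes NEU1 (1.60), GRN (1.42) and CTSD (1.09) and the autophagy receptor SQSTM1 (1.15 ± 0.11) up and TFEB down (−1.39). NRF2 and aryl hydrocarbon receptor targets rose in 7 of 22 and fell in 2 (7 and 2; median 0.37; adjusted p = 0.00826; adjusted p = 0.633 with an estimated correlation), with CYP1A1 at 2.21 ± 0.46, the antioxidant gene TXNRD1 at 1.54 and SLC7A11 at −1.94. Ribosome biogenesis genes fell in 36 of 54 and rose in 0 (38 and 0; median −0.59; adjusted p = 2.6e-09; adjusted p = 0.633 with an estimated correlation), with GAR1 at −1.64 ± 0.15. Interferon response genes fell in 17 of 36 and rose in 3 (18 and 4; median −1.11; adjusted p = 0.00747; adjusted p = 0.633 with an estimated correlation), with IFI44L at −3.69 and MX1 at −1.17. IFI44L is listed at 0 with both inhibitors in MDAMB231 and HCC1806. NF-kB and inflammatory genes fell in 9 of 32 and rose in 1 (9 and 1; median −0.90; adjusted p = 0.0133; adjusted p = 0.633 with an estimated correlation), with CSF2 at −4.01 and SOD2 at 0.43. CSF2 was near 0 with both inhibitors, so its fold and that of IFI44L depend on the pseudocount. The NF-kB and NRF2 calls ended without MDAMB231 (0.197 and 0.0671), and the NRF2 call without the block for the line (0.0560).

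Cell cycle lists fell with the combination, and their medians were lowest in MDAMB231. Of all 14232 tested genes, 2824 fell with the combination. Mitosis genes fell in 10 of 41 cases and rose in 0 (9 and 0 adjusted over the list alone), with a median of −0.95 (adjusted p = 1.7e-04; adjusted p = 0.819 with an estimated correlation). The transcription factor gene FOXM1 (−1.62 ± 0.28), the kinase gene AURKA (−1.49 ± 0.40) and the cyclin gene CCNA2 (−1.28 ± 0.31) were among those that fell. The mitosis median was −2.27 in MDAMB231, −0.37 in SUM159 and −0.11 in HCC1806. DNA replication genes fell in 14 of 45 and rose in 0 (13 and 0 adjusted over the list alone), with a median of −0.57 (adjusted p = 0.00482; adjusted p = 0.850 with an estimated correlation), among them E2F2 (−2.49 ± 0.30) and the replicative helicase gene MCM5 (−1.52 ± 0.21). Their medians were −1.55 in MDAMB231, −0.03 in SUM159 and −0.07 in HCC1806. Without MDAMB231 the mitosis median was −0.26 (0.0558) and that of replication −0.11 (0.811), so both calls ended.

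**Figure D2:**
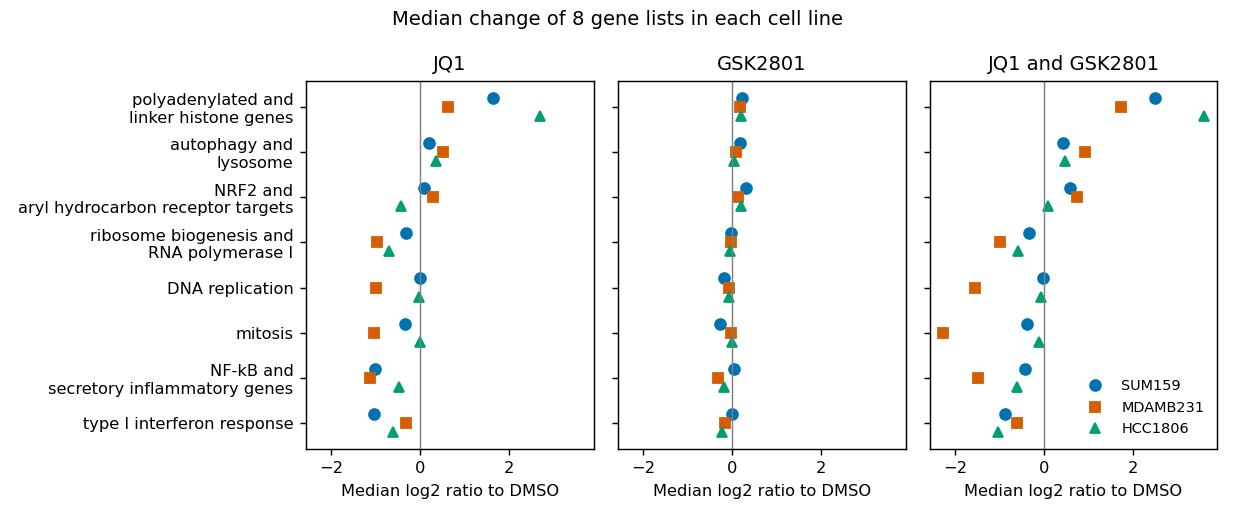
Points give the median log2 ratio to DMSO of 8 gene lists in SUM159, MDAMB231 and HCC1806 (1 library each) with JQ1, GSK2801 or both. The mitosis median with both inhibitors was −2.27 in MDAMB231 and −0.37 and −0.11 in SUM159 and HCC1806, while the histone medians were 1.74, 2.51 and 3.61.

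Over all 14232 tested genes, 2135 rose and 2824 fell with the combination, and a count near those shares says little about its list. The 18 lists that did not pass for the combination gave counts in both directions. They were, as members up and down with the list's size: 7 and 5 of 24 p53 targets (7 and 5 adjusted over the list alone), 10 and 3 of 26 hypoxia genes (10 and 4), 5 and 10 of 29 ATF4 genes (6 and 10), and 3 and 9 of 29 cholesterol synthesis genes (3 and 9). ETS factors gave 0 and 7 of 20 (0 and 7), ERK output genes 3 and 3 of 27 (2 and 2), AP-1 factors 5 and 1 of 12 (5 and 2), apoptosis regulators 3 and 6 of 27 (3 and 6), and bromodomain proteins 5 and 6 of 37 (5 and 6). The immediate early genes FOS (1.55) and EGR1 (1.32) rose. Epithelial genes gave 5 and 5 of 34 (5 and 5), with the junction genes CLDN7 (−1.62) and EPCAM (−1.25) down and JUP (1.43) up, and mesenchymal genes 2 and 4 of 36 (2 and 4), with THBS1 at −2.02 and FBN1 at 1.67. Antigen presentation gave 3 and 5 of 20 (3 and 6), where PSMB8 (−1.63) and TAP2 (−1.46) fell while B2M (0.72) rose. Neuronal genes gave 4 and 2 of 13 (4 and 2), BET inhibitor marker genes 5 and 3 of 12 (5 and 3), and ribosomal protein genes 6 and 6 of 56 (2 and 4), with a median of −0.02 that was −0.14 after quantile normalization (adjusted p = 0.0125). Luminal markers gave 2 and 1 of 14 (2 and 1), fibroblast and adipocyte markers 0 and 2 of 9 (0 and 0), and blood and endothelial markers 0 and 0 of 8 (0 and 0). In 4 of the 26 lists, none of them passing, the median, mean and test differed in sign.

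For the combination 4959 genes passed, 2135 higher and 2824 lower. The same sign in the 3 lines was held by 4905 of them and by 7473 of all 14232 tested genes. Of those passing, 835 higher and 1126 lower genes changed at least 2-fold. The share lower was 56.9% as deposited, 46.9% after TMM rescaling (2592 higher, 2291 lower) and 48.3% after quantile normalization (2486 and 2318). The limma count was 3120 without SUM159, 3156 without MDAMB231 and 2666 without HCC1806. It was 1012 with only the 6 libraries compared, 733 with a threshold of 1.5-fold and 41 without the block for the line.

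The response to the combination was close to that to JQ1. Of the genes JQ1 raised, 1274 (94.0%) also rose with the combination, where independent calls would share 203, and of those it lowered 1701 (91.1%) also fell, where independent calls would share 371. Part of this excess over independent calls may come from the shared controls. Across genes, which are not independent replicates, the mean fold changes correlated at r = 0.920, against 0.499 in simulations of unchanged groups that share the DMSO libraries, with covariances of 0.591 and 0.0610. Between different lines, which share no library, the median correlation over the 12396 genes of higher values was 0.451 for JQ1 with JQ1 (0.445 to 0.515), 0.516 for the combination with itself (0.497 to 0.519), 0.147 for GSK2801 with GSK2801 (0.0978 to 0.163, but as low as 0.0496 over all 14232 genes) and 0.157 for JQ1 with GSK2801 (0.0453 to 0.221). Within the same lines GSK2801 correlated at 0.453 with the combination and at 0.416 with JQ1, below the 0.501 and 0.499 of the simulations, but with covariances of 0.107 and 0.0821, above the simulated 0.0613 and 0.0610. Shared controls add the same covariance with or without a response, so covariances and not correlations would bear on a shared response. The simulations drew on the spread of the additive model, which JQ1 effects that differ between lines may widen. The simulated covariances may thus be too high for GSK2801, and no conclusion on GSK2801 is drawn from them.

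**Figure D3:**
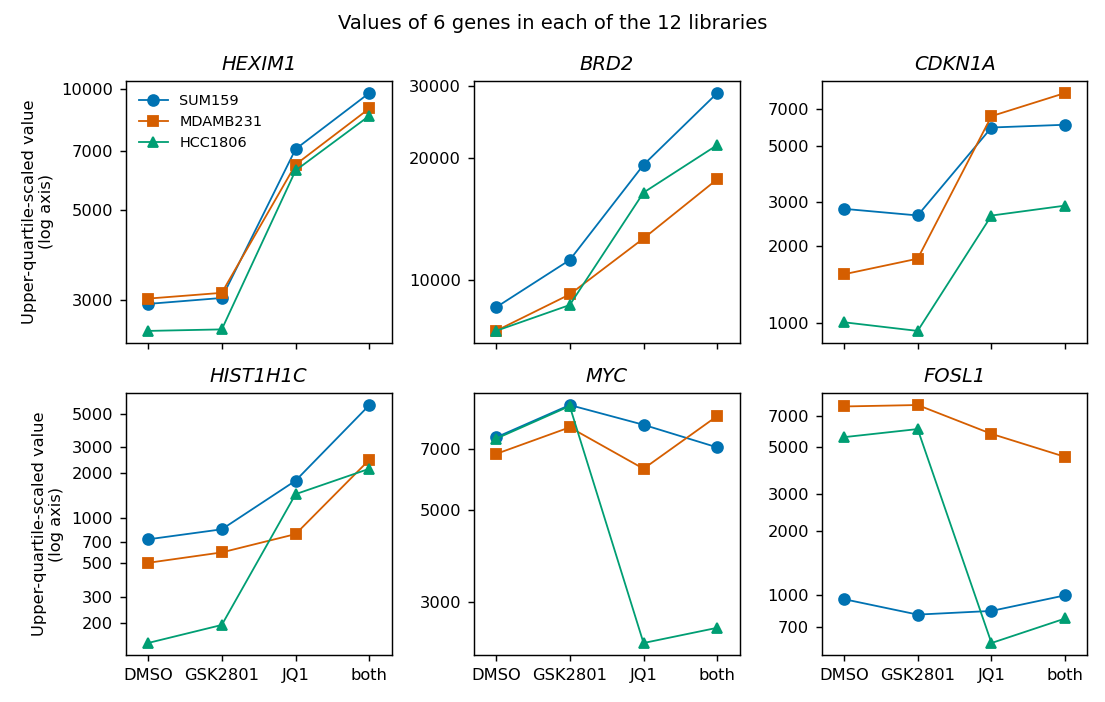
Deposited signal (log axis) of HEXIM1, BRD2, CDKN1A, HIST1H1C, MYC and FOSL1 in the 12 libraries, with 1 point per library and lines joining the 4 treatments of a cell line. HEXIM1 lay between 2510 and 3119 without JQ1 and between 6270 and 9756 with it, and MYC in HCC1806 was 7428 in DMSO and 2389 with JQ1.

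Adding GSK2801 to JQ1 addressed what GSK2801 contributes on top of JQ1. No gene passed. The nuclear envelope gene NRM stood at −1.09 ± 0.12 (adjusted p = 0.152; −1.28, −1.20 and −0.80 in SUM159, MDAMB231 and HCC1806). ANAPC15 (−0.79 ± 0.11), ARPIN (−0.71 ± 0.11), SQSTM1 (0.72 ± 0.11), the lysosomal proton pump gene ATP6V0C (0.59 ± 0.09) and CPT1A (0.60 ± 0.09) had an adjusted p of 0.302. HEXIM1 stood at 0.46 ± 0.08 (0.325), with 0.46, 0.46 and 0.45 in the lines, and BRD2 at 0.49 ± 0.12 (0.453). The limma count of 0 went with 1031 genes at an unadjusted p below 0.05 where chance gives 712, with 0 (2597 unadjusted) in the 6 libraries compared and 0 (1051) with voom weights. In a fit chosen after the data were seen, which gives each line its own JQ1 effect, 871 genes passed, 412 higher and 459 lower (3670 unadjusted), against the planned 0. In that fit the lysosomal and macrophage gene CD68 (1.24 ± 0.09) and HEXIM1 (0.46) were higher, and NRM (−1.09, 0.0111) and MCM5 (−0.66, 0.0126) lower.

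For adding GSK2801 to JQ1, 9 lists passed at the preset correlation and 0 with an estimated one. Autophagy and lysosome genes had a median of 0.23 (adjusted p = 3.2e-09; adjusted p = 0.340 with an estimated correlation; 5 higher adjusted over the list alone), and were similar across lines at 0.22, 0.27 and 0.24. Histone genes stood at 0.92 (3.8e-06; adjusted p = 0.653 with an estimated correlation; 2 higher adjusted over the list alone), with HIST1H2BD at 1.35. NRF2 and aryl hydrocarbon receptor targets stood at 0.32 (1.4e-05; adjusted p = 0.560 with an estimated correlation; 1 higher adjusted over the list alone), with CYP1A1 at 1.98, and BET inhibitor marker genes at 0.25 (0.0174; adjusted p = 0.340 with an estimated correlation; 1 higher adjusted over the list alone). Mitosis genes stood at −0.48 (1.8e-07; adjusted p = 0.814 with an estimated correlation), with medians of −0.09, −1.29 and −0.03 in SUM159, MDAMB231 and HCC1806. DNA replication genes stood at −0.22 (2.6e-04; adjusted p = 0.822 with an estimated correlation), interferon genes at −0.20 (0.00832; adjusted p = 0.653 with an estimated correlation; 2 lower adjusted over the list alone) and hypoxia genes at 0.12 (0.0310; adjusted p = 0.653 with an estimated correlation). Ribosomal protein genes stood at 0.10 (1.5e-04; adjusted p = 0.822 with an estimated correlation), a direction that turned to −0.01 after quantile normalization and to −0.02 without MDAMB231. Over all genes 0 members passed, and 2 bromodomain genes passed adjusted over the list alone although that list did not. Without MDAMB231 the replication (0.177), interferon (0.0696), hypoxia (0.146) and BET marker (0.0917) calls ended as well. The interferon call also ended without HCC1806 (0.556) and without the block for the line (0.0875), the hypoxia call without SUM159 (0.0700) and after quantile normalization (0.257), and the BET marker call by ranks (0.0687).

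Adding JQ1 to GSK2801 addressed what JQ1 contributes when GSK2801 is present. HEXIM1 rose 3.15-fold (1.65 ± 0.08, n = 3 lines), BRD2 2.31-fold (1.21 ± 0.12) and CDKN1A 3.18-fold (1.67 ± 0.21), and BCL2 fell by 0.97 ± 0.17, while BRD3 (0.21 ± 0.09) did not pass. The largest rises were those of HIST2H4B (64.0-fold, log2 SE 0.97), EFR3B (5.50 ± 0.61), DPYSL3 (4.88 ± 0.68), C14orf37 (4.44 ± 0.52) and HIST2H2AA4 (4.07 ± 1.08), followed by HIST1H2BD (3.87 ± 0.27), YPEL1 (3.83 ± 0.25), MAP1A (3.72 ± 0.65), HIST2H4A (3.70 ± 0.63) and HIST1H2BC (3.64 ± 0.50). The largest falls were those of CCAT1 (−5.97 ± 1.06), IL7R (−5.94 ± 0.74), NAV3 (−4.54 ± 0.67), HNF4G (−4.39 ± 0.59) and MYOSLID (−4.33 ± 0.50). FAM196B (−4.28 ± 0.56), the tryptophan pathway gene KYNU (−4.26 ± 0.63), SFTA1P (−4.04 ± 0.40), NUPR1 (−3.99 ± 0.74) and ITGA10 (−3.96 ± 0.85) followed, and KYNU (SUM159), CCAT1 (MDAMB231 and HCC1806), MYOSLID (MDAMB231), NUPR1 and ITGA10 (HCC1806) are listed at 0 with the combination and HIST2H2AA4 with GSK2801 in HCC1806. HIST2H4B is in effect at 0 with GSK2801 in MDAMB231, so these folds depend on the pseudocount. Without SUM159, HIST2H2AA4 (adjusted p = 0.125), CCAT1 (0.0521) and NUPR1 (0.0529) no longer passed, and without HCC1806, HIST2H4B (0.0586), HIST2H2AA4 (0.0688), HIST2H4A (0.0571), NUPR1 (0.0971), ITGA10 (0.0768) and BCL2 (0.0591). With a threshold of 1.5-fold HIST2H2AA4 (0.121), ITGA10 (0.0581) and BCL2 (0.316) were lost.

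For adding JQ1 to GSK2801, 6 lists passed at the preset correlation and 0 with an estimated one. Histone genes rose in 12 of 18 cases (15 adjusted over the list alone; median 2.62; adjusted p = 2.0e-09; adjusted p = 0.738 with an estimated correlation), and autophagy and lysosome genes rose in 15 of 33 and fell in 1 (19 and 1; median 0.48; adjusted p = 3.5e-07; adjusted p = 0.738 with an estimated correlation). Ribosome biogenesis genes fell in 30 of 54 (37; median −0.56; adjusted p = 9.0e-10; adjusted p = 0.738 with an estimated correlation), and interferon genes fell in 13 of 36 and rose in 3 (18 and 3; median −0.93; adjusted p = 0.0259; adjusted p = 0.738 with an estimated correlation). Mitosis genes fell in 9 of 41 (1; median −0.85; adjusted p = 5.8e-04; adjusted p = 0.857 with an estimated correlation) and replication genes in 10 of 45 (7; median −0.50; adjusted p = 0.0259; adjusted p = 0.987 with an estimated correlation). Without MDAMB231 the replication median turned to 0.10 (0.314) and the mitosis call ended (−0.11, 0.582), and the interferon call ended without HCC1806 (0.0783) and without the block (0.0606). In this contrast 4132 genes passed, 1684 higher and 2448 lower. The same sign in the 3 lines was held by 4120 of them and by 7206 of all 14232 tested genes. Of those passing, 577 higher and 904 lower genes changed at least 2-fold. The share lower was 59.2% as deposited, 47.0% after TMM rescaling (2155 and 1909) and 47.5% after quantile normalization (2061 and 1864). The limma count was 2371 without SUM159, 2469 without MDAMB231, 1647 without HCC1806, 2587 without the GSK2801 library of MDAMB231 and 2419 without that of HCC1806. It was 300 with only the 6 libraries compared, 416 with a threshold of 1.5-fold and 3 without the block for the line.

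The departure from additivity addressed whether the response to both inhibitors differed from the sum of the single responses. No gene passed (0 by limma, 171 at unadjusted p below 0.05 where chance gives 712, and 0 with voom weights, 192 unadjusted). With a JQ1 effect for each line it was 0 as well, with 1314 unadjusted. The voom fit and this one were chosen after the data were seen. HEXIM1 stood at 0.42 ± 0.12, with 0.41, 0.41 and 0.44 in SUM159, MDAMB231 and HCC1806, the synaptic vesicle gene SYP at 1.51 ± 0.41, ARPIN at −0.67 ± 0.15, NRM at −0.75 ± 0.18 and EEF1AKMT2 at −0.71 ± 0.18, each with an adjusted p of 1.00. SLC35A2 stood at 6.56 ± 1.73, but is listed at 0 in several libraries, so that value depends on the pseudocount. At the preset correlation 6 lists passed, and 0 with an estimated one. The medians were 0.65 for histone genes (5.7e-04; adjusted p = 0.941 with an estimated correlation), 0.13 for autophagy and lysosome genes (7.9e-05; adjusted p = 0.710 with an estimated correlation) and −0.37 for mitosis genes (1.3e-04; adjusted p = 0.941 with an estimated correlation). They were 0.10 for ribosome biogenesis (0.0304; adjusted p = 0.941 with an estimated correlation), 0.31 for BET inhibitor marker genes (0.0379; adjusted p = 0.710 with an estimated correlation) and 0.20 for ERK output genes (0.0379; adjusted p = 0.710 with an estimated correlation), and 0 members passed in each list, over all genes or adjusted over the list alone. The mitosis median was 0.17 in SUM159, −1.24 in MDAMB231 and −0.05 in HCC1806, and turned to 0.07 without MDAMB231 (0.0780). The BET marker and ERK calls ended after TMM rescaling (0.0512 for each), and with the ribosome biogenesis call also with no low-value filter (0.0616 to 0.0633), after quantile normalization (0.0554 to 0.0792) and with no variance trend (0.0505 to 0.0552). The ERK call ended without SUM159 (0.705) and without HCC1806 (0.118), the ribosome biogenesis call without HCC1806 (0.664), and the BET marker call without MDAMB231 (0.0984) and by ranks (0.0731).

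Within single lines, where no test was run, JQ1 moved 2520 genes at least 2-fold in SUM159 (631 higher, 1889 lower), 2555 in MDAMB231 (1250 and 1305) and 2998 in HCC1806 (1556 and 1442). GSK2801 moved 648, 409 and 596, which fell to 274, 122 and 203 with a pseudocount of 5 and so depended on low values, and the combination moved 3185, 3835 and 3556. In SUM159 with JQ1 the largest log2 ratios were those of DPYSL3 (5.16), SCARA5 (5.05) and EFR3B (4.68), and the lowest those of SULT1B1 (−6.96), DIP2C (−6.47) and the collagen gene COL3A1 (−6.45). In MDAMB231 with both inhibitors the netrin receptor gene UNC5B stood at 5.51 and RIMS2 (−6.90) and MIR137HG (−6.09) were lowest. In HCC1806 with JQ1, EFR3B stood at 7.86, DPYSL3 at 5.86 and IL7R at −8.47. These ratios depend on low values. With a pseudocount of 5 that of EFR3B in HCC1806 moved by over 1.5-fold. So did those of SCARA5, SULT1B1, DIP2C, UNC5B and MIR137HG. With GSK2801 alone DIP2C stood at −5.67 in SUM159 and −5.66 in MDAMB231 but at 3.275 in HCC1806, and with both at −0.40 in SUM159, while ZNF512B stood at 3.73 in HCC1806.

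The contrast of HCC1806 with the other lines addressed whether the line grown in another medium, with the highest JQ1 dose, responded differently. For JQ1, averaged over the presence of GSK2801, 3570 genes differed, 2057 with a higher and 1513 with a lower effect in HCC1806 (5650 at unadjusted p below 0.05). The spread behind these p-values is the departure from additivity within the lines, with no replicate cultures. PDGFRA, a growth factor receptor gene (4.74 ± 0.44), KCNQ3 (4.55 ± 0.37), ZACN (42.1-fold, log2 SE 0.83), RELN (4.81 ± 1.09) and PALM2-AKAP2 (5.12 ± 0.49) had a higher effect. The keratin gene KRT6A (−5.18 ± 0.37), the protease inhibitor gene SERPINB2 (−6.93 ± 0.45), GIMAP4 (−7.18 ± 0.57), TENM2 (−5.78 ± 1.23) and RGS4 (−5.54 ± 1.16) had a lower one. PALM2-AKAP2, KCNQ3 and RELN are listed at 0 in DMSO for HCC1806, PDGFRA with JQ1 and with both for MDAMB231, GIMAP4 in most libraries of SUM159 and MDAMB231, SERPINB2 in all 4 of SUM159, TENM2 in all 4 of MDAMB231 and KRT6A in DMSO and with JQ1 for MDAMB231, so these values depend on the pseudocount. HCC1806 did not stand apart by count, as 3571 genes differed with SUM159 set apart and 4448 with MDAMB231. The share lower was 42.4% as deposited and 54.0% after TMM rescaling (1609 higher, 1886 lower), and the count was 2156 with no variance trend and 562 with a threshold of 1.5-fold. For GSK2801, averaged over the presence of JQ1, 0 genes differed by limma (712 at unadjusted p below 0.05, as many as by chance), with PAG1 (1.17 ± 0.19), the cholesterol exporter gene ABCG1 (1.28 ± 0.22), LINC02188 (2.75 ± 0.45), PRSS23 (−1.12 ± 0.14), COL12A1 (−0.73 ± 0.09) and FAM225B (−3.62 ± 0.42) at the smallest p (adjusted p = 0.276 to 0.523). LINC02188 is listed at 0 for HCC1806 in DMSO and with JQ1, and FAM225B with GSK2801 and with both.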

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

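The gene-level comparison of HCC1806 with the other lines and the other splits of the libraries were planned, whereas the list tests between lines, those with MDAMB231 set apart among them, and the tests on its mitosis genes were chosen only after the results were seen. The tests of differences between lines singled out the 3570 genes whose JQ1 effect differed in HCC1806. The p-values of all these tests rest on departures from additivity within the lines and not on replicate cultures. Among the genes named by rule, EFR3B (2.11), DPYSL3 (2.17), L1CAM (1.91), C14orf37 (2.04), HIST2H4A (2.03), CAPN5 (1.05) and PTPN22 (2.399) had a higher log2 JQ1 effect in HCC1806 than the mean of the other lines. This effect is averaged over the absence and presence of GSK2801, so the libraries with both inhibitors enter it, here and below. IL7R (−3.00), RGS4 (−5.54), CCAT1 (−4.00), NAV3 (−2.84) and IL1B (−4.50) had a lower one. PTPN22 is listed at 7.48 in DMSO and at 0 with JQ1 in HCC1806, so the floor limits its fall there, and EFR3B, L1CAM, CCAT1, RGS4 and IL1B also have values near 0 in a line, so their differences depend on the pseudocount. Of the always named genes, MYC (−1.64), FOSL1 (−2.82), CCND1 (−1.001) and BRD9 (−0.37) had a lower and BAZ2A (0.51) and BAZ2B (0.62) a higher effect. The medium and JQ1 dose of HCC1806 also differ, so these values cannot be told apart by source.

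For JQ1, 10 lists passed the test of HCC1806 against the other lines at the preset correlation and none with an estimated one (adjusted p = 0.561 to 0.892 with an estimated correlation). The median differences were 1.63 for histone genes, 1.45 for neuronal genes, 0.88 for mitosis, 0.56 for DNA replication, 0.45 for p53 targets and 0.27 for bromodomain proteins. They were −0.59 for NRF2 and aryl hydrocarbon receptor targets, −0.45 for mesenchymal and matrix genes, −0.40 for ERK output genes and −0.11 for ribosomal protein genes. With SUM159 set apart mitosis (0.55) and DNA replication (0.72) were higher too, as both lists were lowest in MDAMB231, so these differences do not single out HCC1806. Other lists also passed at the preset correlation with another line set apart, in the direction opposite to HCC1806. With MDAMB231 these were histone genes (−1.41), p53 targets (−0.23), bromodomain proteins (−0.17), NRF2 targets (0.56) and mesenchymal genes (0.53). With SUM159 it was the ribosomal protein list (0.12). Each test sets a line against the mean of the others, so a single differing line can give opposite directions elsewhere. These opposite calls therefore do not tell which line differs. For GSK2801, averaged over the presence of JQ1, 12 lists passed at the preset correlation and none with an estimated one (adjusted p = 0.285 to 0.770). The median differences were 0.38 for mitosis, 0.18 for ERK output genes, 0.18 for epithelial and keratinocyte genes, 0.13 for DNA replication, 0.10 for cholesterol synthesis, 0.0854 for ETS factors and 0.0743 for ribosome biogenesis. They were −0.36 for antigen presentation, −0.29 for interferon response genes, −0.18 for hypoxia and glycolysis, −0.17 for mesenchymal and matrix genes and −0.0832 for ribosomal protein genes.

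The cell cycle lists were lower in MDAMB231, by −1.46 for mitosis and −1.20 for DNA replication in the JQ1 effect and by −0.54 and −0.23 in the GSK2801 effect (adjusted p = 0.519 to 0.601 with an estimated correlation), each averaged over the other inhibitor. With JQ1 alone the mitosis median was −1.05 in MDAMB231, −0.35 in SUM159 and −0.01 in HCC1806, a smaller difference. With GSK2801 alone the mitosis median was −0.02 in MDAMB231, −0.28 in SUM159 and −0.003 in HCC1806, and the replication median −0.06, −0.17 and −0.07, so the lower GSK2801 effect in MDAMB231 came from the library with both inhibitors. With both inhibitors the mitosis median in MDAMB231 was −2.27, and it was −2.19 after TMM rescaling, which argues against the authors' scaling. It was −2.27 over the 40 members with a mean value of at least 1000, which argues against low counts. The lowest correlation of that library with others of its own line was 0.94996, against at most 0.810 between libraries of different lines. This argues against a library of another line. It cannot show a partial mixture or a swap of treatments within MDAMB231. A higher nominal dose is argued against by the labels, which give MDAMB231 100 nM of JQ1, the lowest of the doses, against up to 500 nM. How strongly a given dose acts in each line was not measured. A property of the line may account for the difference of −1.46 (adjusted p = 1.2e-16; 0.519 with an estimated correlation), but the dose separates MDAMB231 as well, so this stays open.

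Outside the gene comparisons, 22 of the entries with date-like names were above the low-value filter, and 7 of them changed with the combination, 7 on adding JQ1 to GSK2801 and 2 with JQ1. A date does not tell which gene it stands for.

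Each treatment contrast pairs 3 libraries with 3, which makes 10 splits, too few for a share under 0.05. For JQ1, 1 split of 10, the real one, gave as many as its 3223 genes and the highest other split gave 0. For the combination it was 1 of 10, with 4959 genes and at most 1 in the other splits, and 0 in those that part all 3 lines. For adding JQ1 to GSK2801 it was 1 of 10, with 4132 genes and 0 in the others. For GSK2801 alone and for adding it to JQ1 all 10 of 10 splits gave 0 genes. For the departure from additivity all 100 of 100 drawn splits gave at least the real 0 genes, as any split must, and the highest other gave 2, so this says nothing about chance. Setting each of the 3 lines apart makes 3 splits, also too few for a share under 0.05, and 3 of 3 gave at least the 3570 genes of HCC1806 for JQ1 (highest other 4448, with MDAMB231). For GSK2801 the real count was 0, which any split reaches (highest other 1). Each split sets 1 line against the mean of the other 2, so a single differing line raises all 3 counts, and the 4448 and 3571 genes with MDAMB231 and SUM159 set apart do not tell which lines differ.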

How the results depend on the processing

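All alternatives were chosen before the data were examined, except the voom weights and the block for each line and JQ1, which were added after the data were seen. Over the named genes, 8346 values under an alternative kept their direction and side of the threshold, 744 kept the direction but no longer passed, 77 newly passed and 0 reversed. Over the gene lists these were 1930, 90, 74 and 6. Of the counts and correlations, 204 stayed near their value and 55 moved, and of the genes within 1 line 69 stayed and 39 moved. Where no cause is given, the cause was not tested.

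Leaving out a line or a single library, which leaves fewer libraries, gave 402–2191 genes for JQ1, 2666–4163 for the combination and 1647–3358 for adding JQ1 to GSK2801. The comparison of HCC1806 with the other lines has no value without HCC1806. Without a line, the lists passing ranged over 5–12 for GSK2801, 4–10 for the combination, 5–11 for adding GSK2801 to JQ1 and 6–11 for the departure from additivity. Without the block for the line, which ignores the pairing, 0, 41 and 3 genes passed for JQ1, the combination and adding JQ1 to GSK2801. With only the 6 libraries compared these were 755, 1012 and 300, with fewer degrees of freedom and a spread taken from those libraries alone. JQ1 effects that differ between lines may make the p-values of the planned model too small for these contrasts. The share of each in the lower counts was not tested. A threshold of 1.5-fold, stricter by construction, gave 120, 733 and 416, and 562 for the JQ1 effect in HCC1806, which was 2156 with no variance trend. The block for each line and JQ1 gave 871 genes for adding GSK2801 to JQ1.

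With an estimated correlation 0 lists passed in each of the 6 contrasts. Correlated members alone do not account for every call that is lost in this way. For the JQ1 effect in HCC1806 against the other lines, the bromodomain list had an estimated correlation of −0.0079, below the preset 0.01. Its camera adjusted p still went from 0.00216 to 0.561. For JQ1, 8 lists passed with no low-value filter, 3 with the stricter one and 9 after quantile normalization. For the departure from additivity 3 passed with no filter, 3 after quantile normalization and 3 with no variance trend. After quantile normalization the test direction of the ribosomal protein genes turned to lower for the combination, where the median went from −0.0158 to −0.142, and their median turned to −0.00787 for adding GSK2801 to JQ1. For the latter it ranged from −0.0209 (without MDAMB231) to 0.168 without a line. Also reversed without MDAMB231, the DNA replication genes ranged from −0.746 to 0.0952 on adding JQ1 to GSK2801 and from −0.272 to 0.102 in the departure from additivity, and there the mitosis genes from −0.638 to 0.0698.

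Genes at 3-fold instead of 2-fold, fewer by construction, were 1151, 221 and 1557 in SUM159 for JQ1, GSK2801 and both, 932, 124 and 1701 in MDAMB231, and 1403, 195 and 1749 in HCC1806. With a pseudocount of 5, which shrinks ratios of low values, GSK2801 gave 274, 122 and 203. The scaling by upper quartile limits statements on the share of genes that rose or fell, and depth limits genes near 0, whose folds depend on the pseudocount.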

Other observations

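The tests of gene span, of genes that mark a line and of genes of 1 exon were written before their results were seen, and the other tests in this part were chosen only after the results were seen. Genes with high values in DMSO in 1 line but not in the others had negative median JQ1 ratios. They were chosen by the same DMSO library that the ratio divides by, so part of a fall can come from the choice. The medians were −0.45 over 407 such genes in SUM159, −0.06 over 293 in MDAMB231 and −0.25 over 686 in HCC1806. In SUM159 30.5% of them, in MDAMB231 15.4% and in HCC1806 24.9% were at least 2-fold lower with JQ1. Of all 14232 tested genes, 1889, 1305 and 1442 were. The MDAMB231 median was close to the −0.059 of matched random lists. With GSK2801 alone the medians of the genes marking each line were 0.12, −0.08 and 0.05, and with both −0.51, −0.17 and −0.30.

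Across genes, the change with GSK2801 alone in a line went along the JQ1 response of the other lines, with which it shares no library, at r = 0.215 in SUM159, 0.167 in MDAMB231 and 0.134 in HCC1806. For GSK2801 added to JQ1 these were 0.172, 0.260 and 0.180 over 12396 genes, which are not independent replicates. The slopes for GSK2801 alone were 0.104, 0.0678 and 0.0670, and on top of JQ1 0.102, 0.151 and 0.112. In SUM159, markers of fibroblasts and adipocytes had a median of −2.23 with JQ1, against −0.73 in MDAMB231 and 0.00 in HCC1806 (9 genes, with none passing over the lines).

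Fewer genes had a small p for GSK2801 alone (161) than the 712 that chance gives. A candidate explanation is that JQ1 effects that differ between lines widen the spread that the additive model shares between contrasts. With a JQ1 effect for each line, 1250 genes had an unadjusted p below 0.05, which fits it, while 0 passed after adjustment (smallest adjusted p = 0.172). Noise unrelated between lines stays open. The correlations of the GSK2801 ratios between lines lay between 0.0978 and 0.163 over the 12396 genes of higher values, and the rank correlations over all 14232 tested genes were 0.144, 0.234 and 0.242, all of which go against it. The lowest Pearson correlation over all genes was 0.0496, just under the 0.05 set for the test, so the measures disagree. The same model gave 871 genes for adding GSK2801 to JQ1, so the planned 0 may depend on the same spread.

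Histone genes rose with JQ1 and with the combination. Reads shared between near-identical copies are argued against, since the 8 members whose values were whole reads in at least 10 of the 12 libraries (5 of them in all 12) had a median log2 change of 2.25 with the combination (3.79 for the others). More cells in DNA replication would raise the replication list, which did not rise with JQ1 or with the combination in any line. With the combination its medians were −0.03 in SUM159, −1.55 in MDAMB231 and −0.07 in HCC1806. The histone medians were 2.51, 1.74 and 3.61. Of the 45 replication genes, 21, 1 and 20 were higher than in DMSO. In MDAMB231 these values argue against more cells in DNA replication, as far as these 45 genes track it. In SUM159 and HCC1806 the medians lay close to no change, which cannot decide it, so it stays open there. The fall of the replication list (median −0.57) rested on MDAMB231, and the median was −0.11 without that line. A bias towards genes of 1 exon is argued against by 213 other protein-coding genes of 1 exon, with a median of 0.11 (−0.08 for genes of more exons). A larger share of histone transcripts with poly(A) tails could also raise these values and was not tested.

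Long genes were tested for lower JQ1 ratios over 11909 genes, and the rank correlations of gene span and ratio lay between −0.0259 in SUM159 and 0.0967 in HCC1806, so span did not go with a fall in all lines. The idea that JQ1 lowers the genes that mark each line was set against matched random lists. The difference was −0.328 in SUM159 and −0.220 in HCC1806, with 0 of 1000 random lists as low, but −0.00283 in MDAMB231, where 471 of 1000 were as low, so it was not borne out as a rule for all lines. The random lists were matched on the DMSO value in the line but not on its excess over the other lines. The choice of genes by that DMSO library may thus add to the differences.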
